A study of Mus musculus with 23 samples.

How the data were processed

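RNA sequencing was done on mouse cells that the labels call ILC2s (group 2 innate lymphoid cells) in 23 libraries. Per the labels' protocols, male donor mice, CAG-GFP transgenic and wild-type, received IL-33 every 2 days over 7 days. Bone marrow and spleen cells without lineage markers (CD11b, Gr1, CD3ε, CD45R/B220, Ter119) and with CD25 were separated by MACS and cultured for 14 days in IL-33, IL-15, IL-7 and IL-2. The cultured cells were sorted as CD45+Lin-ST2+KLRG1+CD127+ and injected into a vein 6 hours after middle cerebral artery occlusion (MCAO, a model of ischemic stroke). Cells were then recovered from blood on day 1 (6 libraries), from blood on day 5 (6 libraries) and from brain on day 5 (6 libraries). A baseline of 5 libraries was taken directly from culture, and whether it passed the final sort is not stated in the sources used here. How the transferred cells were sorted on recovery, and whether each replicate came from a separate animal, is not stated in the sources used here. The labels give a batch for every library, 12 in batch 1 and 11 in batch 2, and both batches hold libraries of all 4 groups.

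Libraries were poly-A selected, random-primed and read as 150 bp pairs per the labels' protocols. Reads were trimmed with fastp and aligned with HISAT2 2.0.5 to the mm10 genome per the submitters' processing notes. The tool that counted reads per gene, its gene annotation, its strand setting and any filter on genes are not given in the sources used here. The deposited table holds 19945 genes and one column per library, and its signal values, named normalized counts by the authors, are gene read counts divided by one factor per library. Whole reads could be recovered from it: in every library 100% of the values were whole multiples of the value of 1 read, within a tolerance of 0.1 read, and the largest deviation was 0.001 read. Median-of-ratios size factors recomputed from those reads over the 7556 genes without a zero differed from the factors in the table by at most 1.3e-09 percent. Symbols were matched to GENCODE M21 for coordinates, with 19931 of 19945 found. No other deposited measurement was used here.

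Recovered reads ran from 11.6 M to 58.1 M per library (M, 1e6 reads), 11.6 M to 16.9 M in batch 1 and 27.8 M to 58.1 M in batch 2. A group with no read in any library is given a floor of 3 reads per library, and a fold against it is printed as a lower bound on the ratio of means over both batches, followed by the bound within one batch where that is clearly lower. Where a group held 1 to 3 reads in all, the ratio of read rates is printed with its 95% counting interval (exact, Clopper-Pearson). Floors and counting intervals cover counting error only, since PCR copies are not independent molecules.

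Genes with a value of at least 10 in at least 5 of the 23 libraries were tested, 15268 in all. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust fitting). All 23 libraries entered one model with the 4 groups and the batch, tests were two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. Folds are log2 differences from this model with their standard errors (SE), and group levels are mean normalized counts with SD. A gene is said to rise, fall or change only where its adjusted p passed the threshold. Within-batch folds are differences of group means of log2(value + 1) in one batch. Where a group held no read in that batch, the pseudocount of 1 sets the fold. Within-batch gene counts come from the same model fitted to one batch.

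A set of 42 gene lists was fixed by name. They cover ILC2 identity, type 2 effectors, type 1 and type 3 modules, the cell cycle, metabolism, ribosomes, interferon and stress responses, migration, residency, receptors, cytokine signalling, apoptosis, antigen presentation, trophic factors and matrix. They also cover markers of other cell types (microglia, monocytes and macrophages, neutrophils, astrocytes, oligodendrocytes, neurons, endothelial and mural cells, choroid plexus and ependyma, erythroid cells, platelets, B cells, T cells, NK cells, dendritic cells, and mast cells, basophils and eosinophils together), mitochondrial transcripts and nuclear-retained RNAs. Lists with 4 or more tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Counts of members are given over all genes tested and adjusted over the list alone. Some lists share genes, such as Cd74 and H2-Ab1 in the antigen presentation and dendritic cell lists.

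The named genes follow one rule. It takes, per comparison, the 8 largest log2 rises and the 8 largest falls among genes past the threshold with a mean of at least 100 in the higher group and the same sign in both batches, leaving out predicted genes and immunoglobulin or T cell receptor variable segments. It adds the fixed genes Gata3, Rora, Il1rl1, Klrg1, Il7r, Il2ra, Il5, Il13, Areg, Il10, Ifng and Mki67, and up to 4 members with the smallest adjusted p of each list described. Apart from the fixed genes, named genes are thus picked from these same libraries for large changes or small p. Their agreement across libraries and alternatives describes them and is not independent support. Il13 and Areg are not among the symbols of the table and were not analysed here, and some genes that the rule selects are not reported here. The model, the comparisons, the lists, this rule and all but 5 of the alternatives were chosen before the data were examined.

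Alternatives changed one choice at a time, except that edgeR changed both the test and the scaling (TMM) and DESeq2 also used its own size factors. They covered the batch term, a replicate block, the pseudocount, the filter on low values, the scaling between libraries, library quality weights, the set of libraries sharing one spread, the eBayes options, the correlation in camera, and leaving out each library in turn. Chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fit without the 4 libraries standing apart from their group, and a fit without genes at 0 in all batch 1 libraries. Also chosen after seeing the data was a fit with the closest libraries averaged, baseline replicates 1 to 3 to 1 library and brain replicates 1 and 3 to 1 library. The list means by batch, the shares and means without one library, the overlap of groups and the bounds within one batch were added after the data were seen as well. The main test was also tested on simulated counts with the spread of these libraries: of genes changed 2-fold it called 0 to 4.5%, of genes changed 4-fold 25.4 to 53.7%, and of genes changed 8-fold 54.5 to 66.7%, and 1.2 to 8.6% of its calls were false. Only 67, 67 and 66 genes were changed by these folds, other genes kept the same mean in all groups, and no batch effect was simulated. The simulations gave 57 to 83 calls, against 4748 to 7513 in the real comparisons other than that between the blood days. These shares therefore do not describe the tests with so many calls. For each comparison, 100 splits of the same libraries, the real one included, were run through the same model.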

Results

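The series asks how transferred group 2 innate lymphoid cells (ILC2s) differ between culture, the blood and the ischemic brain. Granzymes were abundant in the cultured baseline (n = 5), unevenly across libraries: Gzma had a mean normalized count of 1410000 (SD 574000), with 388454.8 in replicate 4 and at least 1567764.6 in the others. Gzmf (chr14:56205263-56211417) had 1300000 (SD 1080000), and was the most abundant gene only in the batch 1 baseline libraries, at 8.59 to 9.29% of the reads. Blood libraries held hemoglobin and platelet transcripts, with Hba-a1 the most abundant gene of blood day 1 replicate 1 at 7.02% of reads, and in brain libraries Ttr, Enpp2 or Ctsd was the most abundant gene. Across genes, the median correlation of log2 values was 0.912 between baseline libraries, 0.842 within blood day 1, 0.907 within blood day 5 and 0.845 within brain, where genes are not independent replicates. It was 0.907 between the blood days, 0.752 and 0.757 between the baseline and each blood day, and 0.469, 0.448 and 0.458 between brain and the baseline, blood day 1 and blood day 5. Libraries standing apart from their own group were blood day 1 replicates 2 (median correlation 0.773) and 6 (0.836), brain replicate 2 (0.795) and baseline replicate 5 (0.852), and all 4 stayed in the analysis. Recovered reads were 12.8 M to 36.8 M in the baseline, 14.7 M to 35.9 M in blood day 1, 12.1 M to 44.0 M in blood day 5 and 11.6 M to 58.1 M in brain (M, 1e6 reads). It is not stated whether each replicate is a separate animal. Whether replicate numbers pair libraries of different groups cannot be told. Same-numbered libraries had correlations of within-batch deviations of -0.104 to 0.189, and differently numbered ones were not computed for reference. Some libraries of a group were far closer than the rest: chi-square per degree of freedom between recovered reads was 4.29 to 13.1 among baseline replicates 1 to 3 and 10.4 between brain replicates 1 and 3, against 47.9 to 1370 for other pairs within a group. Whether these libraries share a source is not stated, the tests treat each library as a replicate, and an alternative averages these closest libraries.

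**Figure D1:**
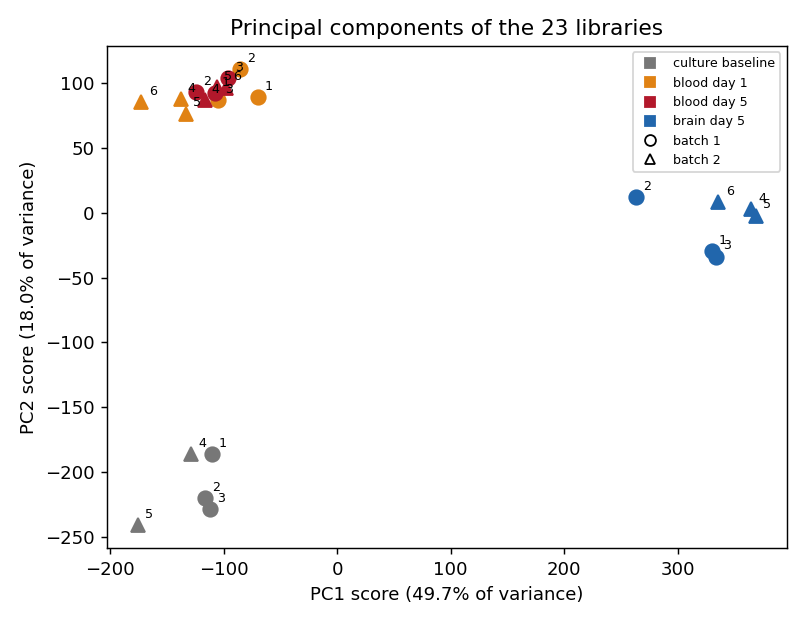
Principal components of log2(normalized count + 1), one point per library, n = 5 baseline, 6 blood day 1, 6 blood day 5 and 6 brain day 5. Component 1 (49.7% of the variance) runs from blood and baseline to brain, and component 2 (18.0%) from the baseline to blood.

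What distinguishes cells recovered from blood on day 1 from the cells in culture? Natural killer and lymphocyte genes made up much of the largest rises: Ncr1, which encodes the receptor NKp46 (chr7:4337724-4345164), rose from 3.52 (SD 5.39) to 15300 (SD 3340), log2 12.56 ± 0.71 (SE), adjusted p = 1.30e-11. Xcl1, which encodes a lymphocyte chemokine (chr1:164931644-164935527), had no read in the baseline and a mean of 3070 in blood, at least 764-fold against a floor of 3 reads per library (619 in batch 1). Itgam was likewise at 0 in the baseline and at 2340 in blood, at least 582-fold on the same floor (539 in batch 1). Lck rose by 11.04 ± 0.88, Gimap4 by 10.50 ± 0.83 and Klre1 by 10.47 ± 0.73. A further pair of the largest rises were platelet genes of very uneven level, Slc6a4 at 43900 (SD 94200) and Gp6 at 11200 (SD 22400), means of 5490 and 2030 without blood day 1 replicate 2, with log2 14.96 and 12.92 in batch 1 but 7.68 and 7.90 in batch 2. Only baseline replicate 4, of batch 2, held reads of either gene in culture, so the pseudocount of 1 sets the batch 1 folds. The largest falls were Ambn (-13.84 ± 0.65), Crisp1 (-13.59 ± 0.83), Gzmf (-13.41 ± 1.36), Gzmd (-12.96 ± 1.31), Gzme (-12.73 ± 1.36), Dsc2 (-12.65 ± 0.81) and Csn1s1 (-11.61 ± 1.00). Csn3 fell from 5920 to no read in any blood day 1 library, at least 1590-fold (984 in batch 1). The granzyme falls were smaller in batch 2: Gzmf was at -16.60 in batch 1 and -9.28 in batch 2, Gzmd at -16.01 and -8.89, Gzme at -16.45 and -7.86, and Csn1s1 likewise at -15.19 and -7.17.

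Genes of lymphocyte recirculation and quiescence were higher in blood day 1 than in culture: of 23 tested, 17 rose and 1 fell (19 and 1 adjusted over the list alone), adjusted p = 1.15e-10 and 0.00627 with an estimated correlation. Klf2 rose by 5.15 ± 0.32, S1pr5 by 9.83 ± 0.63 (7.51 in batch 1 and 12.81 in batch 2) and Tcf7 by 9.48 ± 0.77. The NK cell list (8 of 11 rose, 2 fell; 8 and 3 over the list alone) gave 1.02e-05 and 0.0404, with Klrk1 up 10.03 ± 0.63. Klrc1 had 3 reads in all baseline libraries together, a ratio of 2280 (95% counting interval 781 to 11100). Against these rises, the share of all NK list transcripts in the normalized total was 6.70 ± 2.48% (SD) in the baseline and 1.03 ± 0.367% in blood day 1, since the list holds Gzma and Prf1. The interferon-stimulated list rose in 19 of 32 and fell in 0 (20 and 0 over the list alone, 6.33e-07, and adjusted p = 0.0605 with an estimated correlation). Rtp4 rose by 6.60 ± 0.47, Usp18 up 6.08 ± 0.54 and Ifit1 up 8.38 ± 0.79. The type 3 module rose in 7 of 10 and fell in 1 (8 and 1 over the list alone, 4.61e-04, and adjusted p = 0.0652 with an estimated correlation). Chemokine receptors and integrins rose in 15 of 29 and fell in 4 (15 and 4 over the list alone, 6.12e-04, and adjusted p = 0.0652 with an estimated correlation). The type 1 and cytotoxic module rose in 11 of 21 and fell in 6 (11 and 7 over the list alone, 0.0199, and adjusted p = 0.249 with an estimated correlation), the falls including Gzmb (-5.94 ± 0.54).

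Amino acid, cholesterol, glycolysis and ribosomal protein lists were lower in blood day 1, while oxidative phosphorylation was not called (6 of 35 rose and 1 fell; 2 and 0 over the list alone, 0.861). The amino acid and one-carbon list fell in 20 of 27 and rose in 0 (20 over the list alone, 1.15e-10, and 0.00627 with an estimated correlation), including Asns (-5.56 ± 0.65) and Mthfd2 (-2.58 ± 0.23). Cholesterol biosynthesis fell in 16 of 23 (16 over the list alone, 1.67e-06, and 0.0457), including Hmgcs1 (-3.54 ± 0.34) and Sqle (-2.51 ± 0.37). Ribosomal proteins fell in 40 of 42 (41 over the list alone, 2.00e-19, and adjusted p = 0.0957 with an estimated correlation), with Rpl23 down to 2160 from 25000. Glycolysis fell in 10 of 16 (10 over the list alone, 1.31e-05, and adjusted p = 0.0768 with an estimated correlation), led by Slc2a1 (-2.21 ± 0.26) and Gpi1 (-2 ± 0.27). Hypoxia targets fell in 9 of 21 and rose in 2 (9 and 2 over the list alone, 0.00101, and adjusted p = 0.111 with an estimated correlation). Egln3 fell from 9530 to 108 and Bnip3 from 9080 to 356. Heat shock and unfolded protein response genes fell in 10 of 25 and rose in 2 (11 and 3 over the list alone, 0.00489, and adjusted p = 0.0653 with an estimated correlation), such as Hsp90b1 (-2.40 ± 0.35) and Hspa5 (-1.45 ± 0.27). The IL-2 and STAT5 list fell in 8 of 22 and rose in 4 (9 and 4 over the list alone, 0.0148, and adjusted p = 0.114 with an estimated correlation). Cish fell by 3.25 ± 0.36. G2/M genes fell in 5 of 24 (5 over the list alone, 0.0144, and adjusted p = 0.576 with an estimated correlation) and S phase genes in 7 of 28 (7 over the list alone, 0.00328, and adjusted p = 0.529 with an estimated correlation). Both cell cycle lists fell in batch 1 only: the difference of the list mean was -3.57 in batch 1 and 1.37 in batch 2 for G2/M, and -3.31 and 1.31 for S phase. Neither was called with the closest libraries averaged (0.323 and 0.25).

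Markers of other blood cells rose in the blood libraries, and single libraries carried some of the shares. Platelet markers rose in 12 of 12 (12 over the list alone, 2.44e-09, and adjusted p = 0.114 with an estimated correlation), from 0.0158 ± 0.0229% to 1.61 ± 2.22% of the normalized total, with Itga2b at 127000 (SD 229000; 34000 without blood day 1 replicate 2). The baseline share was 0.00681% without baseline replicate 4, the share in blood 0.708% without blood day 1 replicate 2, which held 6.14%, and Itga2b rose by 10.47 in batch 1 and 4.65 in batch 2. Erythroid markers rose in 7 of 8 (7 over the list alone, 1.02e-05, and adjusted p = 0.0777 with an estimated correlation), from 0.0978 to 3.01 ± 2.93%, with Alas2 up 7.10 ± 0.95. Without baseline replicate 4 and blood day 1 replicate 1 these shares were 0.0142 and 1.85%. B cell markers rose in 12 of 15 and fell in 1 (12 and 1 over the list alone, 6.44e-08, and adjusted p = 0.089 with an estimated correlation), from 0.0301 to 0.654 ± 0.244%, with Cd79a up 6.91 ± 0.62 although B220 and Ter119 were among the antigens used to remove lineage-positive cells before culture. MHC class II genes rose in 10 of 10 (10 over the list alone, 8.29e-10, and adjusted p = 0.0653 with an estimated correlation) and dendritic cell markers in 11 of 13 (11 over the list alone, 1.67e-06, and 0.0457), both lists including Cd74 (159000 against 2060) and H2-Ab1 (60800 against 783). Neutrophil markers rose in 13 of 15 and fell in 1 (14 and 1 over the list alone, 1.67e-06, and adjusted p = 0.134 with an estimated correlation). Monocyte markers rose in 9 of 13 (10 over the list alone, 1.06e-05, and adjusted p = 0.0652 with an estimated correlation) and mast cell, basophil and eosinophil markers in 7 of 13 (7 over the list alone, 8.95e-04, and adjusted p = 0.268 with an estimated correlation). T cell markers rose in 7 of 16 and fell in 3 (9 and 5 over the list alone, 0.0138, and adjusted p = 0.258 with an estimated correlation), yet their share was 0.707 ± 0.354% in the baseline and 0.392 ± 0.101% in blood.

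ILC2 genes moved in both directions. The identity list rose in 8 of 23 and fell in 7 (9 and 9 over the list alone) and did not pass as a list (0.847). Il7r (chr15:9505788-9530176) rose from 24.5 (SD 29.6; 75.8 in replicate 1 and at most 18.3 in the others) to 1390 (SD 761), log2 6.57 ± 0.75, Rora by 3.57 ± 0.76 and Gata3 (chr2:9857078-9890034) by 2.12 ± 0.63 (adjusted p = 0.013; 7.51e-08 to 0.126 over the alternatives, 0.126 with the closest libraries averaged). Il1rl1, which encodes the IL-33 receptor ST2 (chr1:40429570-40465415), had 3 reads in all in the baseline and a mean of 135 (SD 116) in blood day 1, a ratio of 216 (95% counting interval 73.8 to 1050), with 5 of 6 blood libraries above the baseline. Il2ra (chr2:11642807-11693193) fell by 6.82 ± 0.67, from 15300 to 173, and Il10 from 313 (SD 408; 43.8 in baseline replicate 2 to 990.6 in replicate 5) to 1.39 (0.262 without blood day 1 replicate 3). Klrg1 (chr6:122270596-122282882) fell by 1.93 ± 0.55 (adjusted p = 0.0093; 2.23e-04 to 0.0537 over the alternatives, -1.60 and 0.0537 without the 4 libraries standing apart). Ifng fell by 2.21 ± 0.78 (adjusted p = 0.035; 2.56e-05 to 0.25 over the alternatives, 0.25 with the closest libraries averaged). It was not called with a pseudocount of 0.5 (0.0572), equal library totals (0.0705), only the libraries of both groups (0.056) or edgeR with TMM scaling (0.0617). Its call was also lost with a replicate block (0.0554) and without the 4 libraries standing apart (0.0597). It fell by 3.73 in batch 1 and 0.23 in batch 2, and lost its call without baseline replicate 1, 2 or 3 (0.0915, 0.0926 and 0.0868) or blood day 1 replicate 1 or 2 (0.0664 and 0.0912). Mki67 fell by 3.84 ± 1.29 (0.0253; 2.07e-07 to 0.221 over the alternatives, 0.221 with the closest libraries averaged). It was not called with only the libraries of both groups (0.119) or without the 4 libraries standing apart (0.155). It fell by 6.90 in batch 1 and 0.04 in batch 2, and lost its call without baseline replicate 1, 2 or 3 (0.0664, 0.0672 and 0.0671) or blood day 1 replicate 2 (0.0575), which had no Mki67 read.

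**Figure D2:**
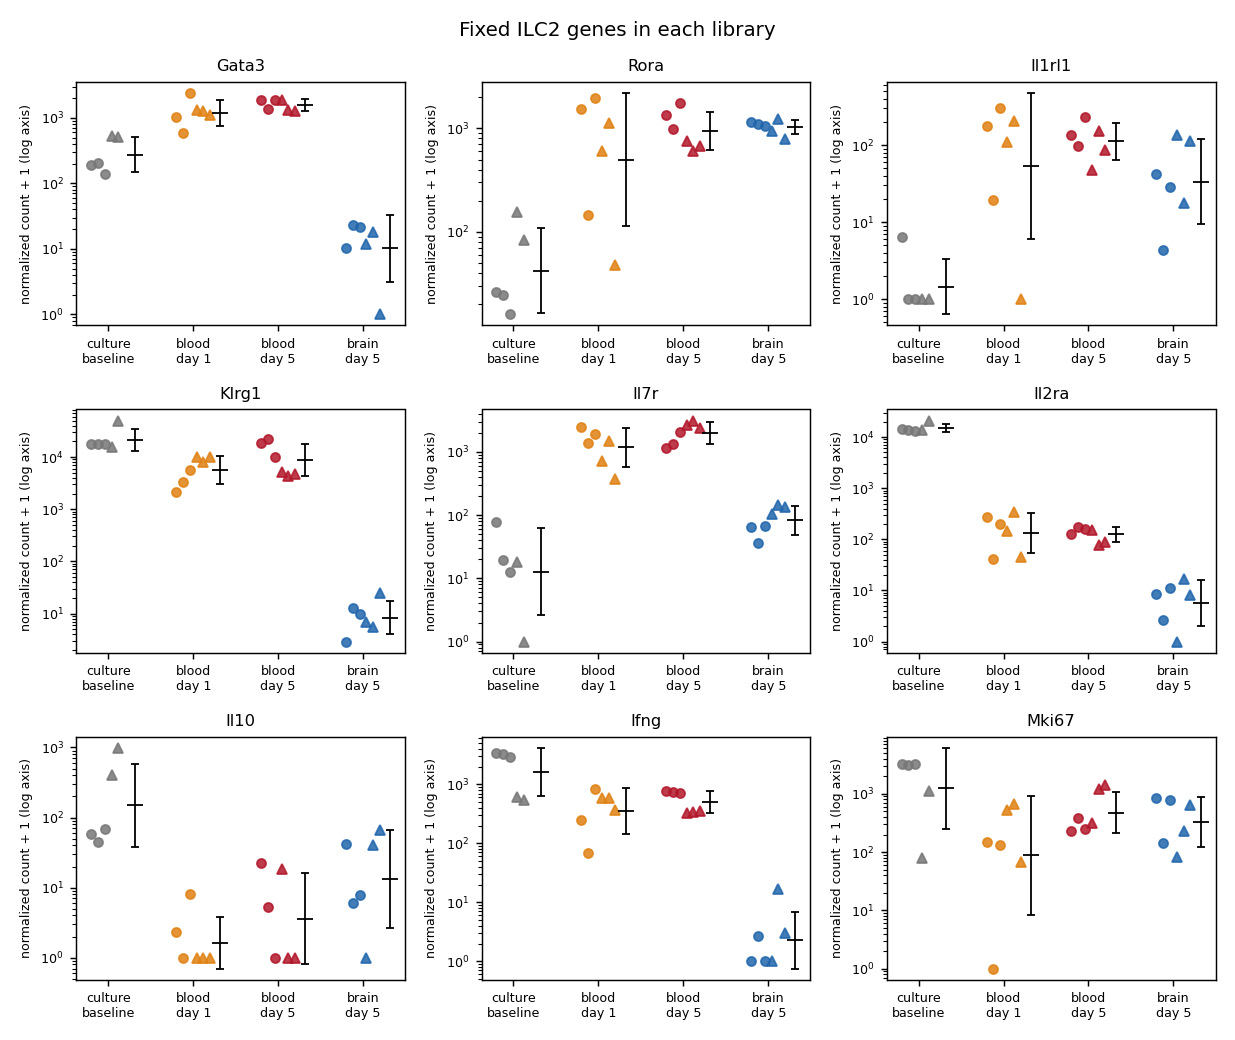
Normalized count + 1 on a log axis for 9 genes fixed in advance, by group. Circles are batch 1 and triangles batch 2 libraries, and bars with whiskers are the mean ± SD on the log scale (n = 5, 6, 6 and 6). Il2ra has a mean of 15300 in the baseline and 7.06 in brain, while Il7r has 24.5 in the baseline, 2130 in blood day 5 and 90.6 in brain.

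In limma with the batch in the model (n = 6 against 5), 2770 genes were higher and 2135 lower in blood day 1 at adjusted p < 0.05, of 15268 tested, and 97.7% had the same sign in both batches. The alternatives gave 5274 higher and 4647 lower with library quality weights, 1370 lower with only the libraries of both groups and 1222 lower with the closest libraries averaged. Of 51 called genes named for this comparison, 49 had all 6 blood libraries on the side of the change from the baseline mean, the exceptions being Il1rl1 and Rora (46.4 in blood day 1 replicate 6). The 2 groups did not overlap in 47 of them, which the choice of named genes from these same libraries favours. Fitted by batch, 4911 genes passed in batch 1 and 2677 in batch 2. Among 100 splits of the same libraries the real one gave the most genes, 4905 against 3460 for the next, so a random division of the libraries is excluded as its source.

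By day 5 in blood, which differences from culture remain? Ncr1 stood at 18000 (SD 9970), log2 12.63 ± 0.71 above culture, and Lck at 32100 (10.74 ± 0.88). Genes with no read in culture included Itgam (at least 1420-fold, 1330 in batch 1), Cym (at least 974-fold, 685 in batch 2) and Klra1, which encodes an NK receptor (at least 635-fold, 449 in batch 1), all on a floor of 3 reads per library. Klra7 had 3 baseline reads, a ratio of 4030 (95% counting interval 1380 to 19500). The mast cell and basophil proteases Cma1 and Prss34 rose by 10.88 ± 0.90 and 11.10 ± 1.98. Gzmf was down to 3 reads in 6 libraries, a baseline excess of 2420000-fold (95% counting interval 828000 to 11700000). The log2 fold was -20.99 in batch 1 and -16.32 in batch 2, the latter a smaller fold than the interval holds. No batch 1 library of blood day 5 held a Gzmf read, so the pseudocount of 1 sets the batch 1 fold. It therefore cannot be set against that interval. No read was left of Gzmd (at least 186000-fold lower, 29500 in batch 2), Gzme (70600, and 10400 in batch 2), Ambn (9880, and 3250 in batch 2), Dsc2 (8330, and 5970 in batch 1) or Csn1s1 (7730, and 1670 in batch 2), and Crisp1 fell by 13.83 ± 0.83.

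The recirculation list rose in 18 of 23 and fell in 0 (18 over the list alone, adjusted p = 6.32e-13, and 0.00252 with an estimated correlation), with Klf2 at 13300 (SD 700). Immediate early and NF-kB genes rose in 19 of 33 and fell in 5 (20 and 5 over the list alone, 6.06e-04, and adjusted p = 0.147 with an estimated correlation): Fos by 6.08 ± 0.44, Zfp36 by 3.95 ± 0.34 and Btg2 by 3.72 ± 0.34, while Bhlhe40 fell by 2.20 ± 0.24. Amino acid genes fell in 20 of 27 (20 over the list alone, 1.73e-12, and 0.00252). Asns fell by 6.19 ± 0.65 and Mthfd2 by 3.02 ± 0.23. Heat shock and unfolded protein response genes fell in 13 of 25 and rose in 2 (13 and 2 over the list alone, 2.36e-05, and 0.0134), such as Hspe1 (-2.13 ± 0.30) and Canx (-1.80 ± 0.25). Ribosomal proteins fell in 40 of 42 (40 over the list alone, 2.92e-23, and adjusted p = 0.0659 with an estimated correlation), glycolysis in 9 of 16 (11, and 1 rising; 9.84e-06, and adjusted p = 0.0659 with an estimated correlation), cholesterol biosynthesis in 10 of 23 (10 over the list alone, 5.08e-06, and adjusted p = 0.052 with an estimated correlation). Trophic and repair factors rose in 5 of 17 and fell in 5 (5 and 5 over the list alone, 0.41). Pdgfb rose by 7.93 ± 0.57 and Spp1 (chr5:104435118-104441050) down from 347000 (SD 357000) to 372.

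Markers of other blood cells were again higher in blood. Neutrophil markers rose in 14 of 15 (14 over the list alone, 1.13e-09, and adjusted p = 0.0659 with an estimated correlation), from 0.0125 ± 0.0133% to 1.37 ± 1.25% of the normalized total. S100a8 was at 63800 (SD 77000; 214548.6 in replicate 6 and at most 64490.6 in the others), and Il1b rose by 9.26 ± 0.79 (6.62 in batch 1 and 12.76 in batch 2). The neutrophil shares were 0.00661% without baseline replicate 1 and 0.934% without blood day 5 replicate 6. Monocyte markers rose in 11 of 13 (12 and 1 falling; 7.59e-07, and 0.0431), Cd74 by 7.20 ± 0.54 and Apoe by 5.26 ± 0.40 among myeloid and antigen presentation genes. MHC class II genes rose in 10 of 10 (10 over the list alone, 9.37e-10, and adjusted p = 0.0659 with an estimated correlation). B cell markers rose in 14 of 15 (14 and 1 falling; 2.43e-09, and adjusted p = 0.0659 with an estimated correlation) to 1.04 ± 0.31%, platelet markers in 12 of 12 (12 over the list alone, 8.35e-08, and adjusted p = 0.147 with an estimated correlation) to 0.780 ± 0.572%, and erythroid markers in 8 of 8 (8 over the list alone, 1.41e-04, and adjusted p = 0.117 with an estimated correlation) to 1.61 ± 1.39%. NK markers rose in 8 of 11 and fell in 2 (8 and 2 over the list alone, 1.00e-05, and 0.0296). T cell markers rose in 7 of 16 and fell in 4 (7 and 4 over the list alone, 0.0904).

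Il7r reached 2130 (SD 766), log2 7.34 ± 0.75 above culture, Rora rose by 4.50 ± 0.76 and Gata3 by 2.53 ± 0.63 (adjusted p = 0.00335). Il1rl1 had a ratio of 161 (95% counting interval 54.9 to 782), with a blood mean of 125 (SD 64.4). Il2ra fell by 6.90 ± 0.67 and Il10 by 5.39 ± 1.17. Klrg1 did not pass (-1.31 ± 0.55, 0.074; 0.028 to 0.215 over the alternatives), -0.16 in batch 1 and -2.56 in batch 2, and was called without blood day 5 replicate 1 (0.0392) or 2 (0.028) and with a pseudocount of 5 (0.0479). Ifng did not pass (-1.67 ± 0.78, 0.115; 6.18e-05 to 0.482 over the alternatives), and was called with library quality weights (6.18e-05), with only the libraries of both groups (7.99e-04), in DESeq2 (0.0349) and without the 4 libraries standing apart (0.0345). Mki67 did not pass (-1.40 ± 1.29, 0.463; 1.02e-05 to 0.941 over the alternatives), at -3.53 in batch 1 and 1.47 in batch 2, and was called with quality weights (1.02e-05). The identity list rose in 9 of 23 and fell in 6 (9 and 8 over the list alone, 0.622).

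For blood day 5 against culture limma called 3000 genes higher and 1748 lower (n = 6 against 5), 98.3% with the same sign in both batches, 4212 in batch 1 alone and 3447 in batch 2 alone. The alternatives gave 5133 higher and 4500 lower with library quality weights, 2802 lower without the 4 libraries standing apart and 1155 lower with equal library totals. All 36 called genes named here, mostly picked for their change in these libraries, had 6 of 6 blood libraries on the side of the change from the baseline mean, with no overlap of the groups. The share of calls that were higher was 63.2%, and 76.0% when libraries were scaled to equal totals. The real grouping gave more genes than any other of 100 splits (4748 against 3459), which excludes a random division as its source.

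How do cells from the brain differ from the cells in culture? Most of the largest rises were genes with no read in culture: Col3a1 at 97200 (SD 66800, at least 24200-fold, 8090 in batch 1), Igfbp5 (at least 11700-fold), Opalin (11500, and 2120 in batch 1), Serpina3n (8040, and 4310 in batch 1), Slc47a1 (8040, and 6270 in batch 2), Bgn (7560) and Islr (5430, and 4160 in batch 1), all on a floor of 3 reads per library. Ttr, the choroid plexus transthyretin gene (chr18:20665280-20674321), rose from 92.8 to 542000 (SD 295000), log2 15.57 ± 2.26, at 19.44 in batch 1 and 10.38 in batch 2. The batch 1 baseline libraries held no Ttr read, so the pseudocount of 1 sets the batch 1 fold. Brain levels overlapped between batches, at 570973.7 to 1000727.2 in batch 1 and 207773.8 to 615681.6 in batch 2. The cytotoxic genes were nearly gone: Gzma (chr13:113093825-113100981) fell from 1410000 to 98.3 (SD 130; 359.1 in brain replicate 6 and at most 77.7 in the others), log2 -14.33 ± 0.62. Gzmb (-14.58 ± 0.54), Gzmc (-15.66 ± 0.90), Gzmd (-16.5 ± 1.31), Gzme (-15.05 ± 1.36), Gzmf (-16.99 ± 1.36) and Prf1 (chr10:61297833-61304680, -13.63 ± 0.68) fell too, with Gzmd at -19.79 in batch 1 and -12.18 in batch 2. Ambn had 2 reads in brain, a culture excess of 79500-fold (95% counting interval 22000 to 657000). The log2 fold was -15.51 in batch 1 and -11.79 in batch 2, the latter a smaller fold than the interval holds. No batch 1 brain library held an Ambn read, so the pseudocount of 1 sets the batch 1 fold. It therefore cannot be set against that interval.

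T cell, NK, type 1 and receptor lists fell in brain against culture, while the recirculation list did not pass (14 of 23 rose and 4 fell; 14 and 4 over the list alone, adjusted p = 0.475). T cell markers fell in 11 of 16 and rose in 2 (11 and 2 over the list alone, adjusted p = 3.53e-11, and 0.00898 with an estimated correlation), with Cd3d (chr9:44981786-44987339) down from 29200 to 13.1 and Trbc1 from 23500 to 10.2. The type 1 module fell in 12 of 21 and rose in 4 (13 and 5 over the list alone, 8.66e-08, and 0.0152), NK markers fell in 6 of 11 (6 over the list alone, 2.12e-05, and 0.0254), and inhibitory and costimulatory receptors fell in 13 of 24 and rose in 4 (13 and 5 over the list alone, 4.10e-06, and 0.01). The IL-2 and STAT5 list fell in 13 of 22 and rose in 2 (14 and 2 over the list alone, 6.76e-09, and 0.00402), including Il2rb (-10.36 ± 0.26) and Tnfrsf9 (-11.66 ± 0.62). Amino acid genes fell in 21 of 27 and rose in 1 (21 and 1 over the list alone, 2.57e-09, and 0.00898), such as Mthfd2 (-3.41 ± 0.23) and Slc1a5 (-3.25 ± 0.28). Ribosomal proteins fell in 40 of 42 (41 over the list alone, 2.06e-23, and adjusted p = 0.0908 with an estimated correlation), Rps18 by 3.17 ± 0.27 and Rpl32 by 3.12 ± 0.26. Immediate early genes rose in 18 of 33 and fell in 9 (18 and 9 over the list alone, 0.598), with Fos (chr12:85473890-85477273) up 8.60 ± 0.44 and Zfp36 up 5.11 ± 0.34. Trophic factors rose in 9 of 17 and fell in 2 (9 and 4 over the list alone, 0.264). Igf1 rose by 9.96 ± 0.94 and Penk stood at 4790 (3050 without brain replicate 2) against 17.9. Chemokine receptors and integrins rose in 9 of 29 and fell in 11 (9 and 11), and the list was called lower (0.0355, and adjusted p = 0.214 with an estimated correlation), though not with the closest libraries averaged, although its median and mean were above 0 and its list mean moved by -0.26 in batch 1 and 1.16 in batch 2.

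Brain cell markers rose in the same libraries. Microglia markers rose in 14 of 15 (14 over the list alone, 8.37e-08, and adjusted p = 0.0817 with an estimated correlation), to 2.24 ± 1.19% of the normalized total, with Csf1r at 53700, Cx3cr1 at 16600 and Trem2 at 16100. Oligodendrocyte markers rose in 15 of 15 (15 over the list alone, 1.33e-07, and adjusted p = 0.133 with an estimated correlation), to 1.48 ± 0.296%, with Mag at 28500. Choroid plexus and ependymal markers rose in 10 of 10 (10 over the list alone, 1.53e-05, and adjusted p = 0.0908 with an estimated correlation), to 4.09 ± 2.3%, with Foxj1 at least 888-fold (625 in batch 1) and Prlr at least 3220-fold (889 in batch 1) above a floor of 3 reads. Astrocyte markers rose in 14 of 14 (14 over the list alone, 6.40e-05, and adjusted p = 0.145 with an estimated correlation), with Sox9 at least 1240-fold higher (601 in batch 1) and Aqp4 up 10.57 ± 1.00. Endothelial and mural markers rose in 12 of 14 (13 over the list alone, 0.00103, and adjusted p = 0.145 with an estimated correlation), with Rgs5 at least 1280-fold higher (368 in batch 1) and Flt1 up 8.32 ± 0.79. Monocyte markers rose in 11 of 13 and fell in 1 (11 and 1 over the list alone, 0.00194, and adjusted p = 0.152 with an estimated correlation), and Apoe reached 506000 (SD 271000). Neuron markers rose in 10 of 14 (10 over the list alone, 0.0641), such as Tubb3 (5.17 ± 0.62) and Syp, which had 1 read in culture and a ratio of 2670 (95% counting interval 479 to 105000).

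Of the ILC2 genes, 5 of 23 in the identity list rose and 12 fell in brain against culture (5 and 12 over the list alone, 3.39e-05, and adjusted p = 0.0511 with an estimated correlation). Gata3 fell to 13.3 (SD 8.29), -4.73 ± 0.63, Klrg1 to 9.40 (SD 7.68), -11.34 ± 0.55, Il2ra to 7.06 (SD 5.68), -11.33 ± 0.67, and Ifng to 3.28 (0.731 without brain replicate 5), -9.47 ± 0.78. Rora rose by 4.64 ± 0.76 and Il1rl1 had a ratio of 108 (95% counting interval 36.8 to 525), at a mean of 56.1. Brain cell markers rose in the same libraries, and whether the Rora and Il1rl1 reads come from ILC2s was not tested. Il7r rose by 2.73 ± 0.75 (0.00394; 4.51e-04 to 0.0907 over the alternatives, 0.0907 in edgeR with TMM scaling), 1.03 in batch 1 and 4.89 in batch 2. Il10 fell by 3.5 ± 1.17 (0.0159; 0.00258 to 0.302), and lost its call without baseline replicate 5 (0.0672). Its call was also lost with library quality weights (0.302), in edgeR with TMM scaling (0.0501) and without the 4 libraries standing apart (0.13). Mki67 did not pass (-1.96 ± 1.29, 0.222; 6.94e-05 to 0.575), and was called without baseline replicate 4 (0.0399). It was also called with library quality weights (6.94e-05), in edgeR with TMM scaling (0.022) and in DESeq2 (0.0226).

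Against culture, limma called 5733 genes higher and 1780 lower in brain (n = 6 against 5), 99.2% with the same sign in both batches, with 6085 called in batch 1 alone and 6448 in batch 2 alone. The number lower was 3054 with library quality weights and 2746 in edgeR with TMM scaling. All 49 called genes named here, mostly picked for their change in these libraries, had 6 of 6 brain libraries on the side of the change from the baseline mean. In 46 of them the groups did not overlap (Il1rl1, Il7r and Il10 did). No other of 100 splits gave as many genes (7513 against 5746 for the next), so a random division of the libraries is excluded as its source.

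Does a further stay in the blood, from day 1 to day 5, change the transcripts? Few genes passed, and several are myeloid or immediate early genes. Dusp1, an immediate early phosphatase gene (chr17:26505590-26562128), rose from 2340 (SD 1330) to 33300 (SD 13100), log2 3.90 ± 0.47, adjusted p = 4.46e-04. Cxcl2 (chr5:90903871-90905938) rose by 7.43 ± 0.98 (0.00108; 2.24e-08 to 0.0739 over the alternatives, 0.0739 in edgeR), Steap4 by 6.95 ± 1.04, Il1b (chr2:129364570-129371139) by 4.52 ± 0.75, from 218 to 5120, and Cd14 by 2.95 ± 0.47. Foxd4 rose by 6.2 ± 1.15 (0.0224; 2.68e-04 to 0.691) and Dmxl2 by 6.12 ± 1.11 (0.0183; 0.00511 to 0.436), at 3.42 and 8.97 (Foxd4) and 3.56 and 8.68 (Dmxl2) in batches 1 and 2. Neither was called in edgeR with TMM scaling (0.691 and 0.436), with the closest libraries averaged (0.0634 and 0.0634), with a replicate block (0.0614 and 0.0505) or with only the libraries of both groups (0.151 each). Foxd4 was also not called in DESeq2 (0.509) or without the 4 libraries standing apart (0.138). Foxd4 lost its call without blood day 1 replicate 2, 4, 5 or 6 (0.0538, 0.0674, 0.0812 and 0.0749) or blood day 5 replicate 4, 5 or 6 (0.087, 0.0743 and 0.0786). Dmxl2 lost it without blood day 1 replicate 4 or 5 (0.0612 and 0.0758) or blood day 5 replicate 4, 5 or 6 (0.0651, 0.0743 and 0.0688). Fos rose by 2.35 ± 0.42 (0.0172; 1.39e-05 to 0.0679), and lost its call without blood day 1 replicate 5 (0.0597) or blood day 5 replicate 6 (0.0643). It was also not called in edgeR with TMM scaling (0.0537) or without the 4 libraries standing apart (0.0679). Junb rose by 1.94 ± 0.35 (0.0183; 5.41e-06 to 0.0758), and lost its call without blood day 1 replicate 4 (0.0558) or 5 (0.0758) or blood day 5 replicate 1 (0.0665), 2 (0.0578) or 6 (0.0554), with a replicate block (0.0553) and in edgeR with TMM scaling (0.0739). The only gene that fell was D630024D03Rik (-5.11 ± 0.92, 0.0183), and Myl2 (4.43 ± 0.64), Trnp1 (4.4 ± 0.76), Jam3 (4.01 ± 0.77), Mir7678 (3.93 ± 0.68), Amer2 (3.7 ± 0.72) and Irs2 (1.85 ± 0.31) rose as well. These 7 lie outside the rule for named genes and were chosen after their values were seen.

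**Figure D3:**
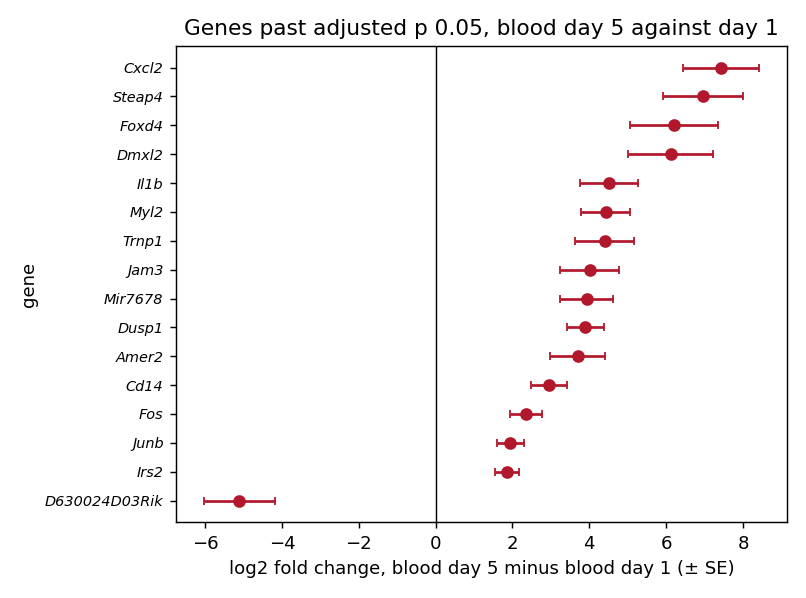
Log2 difference, blood day 5 minus blood day 1, with SE for the 16 genes past the threshold (n = 6 and 6). There are 15 genes to the right of 0 and 1 to the left, with Cxcl2 at 7.43 ± 0.98 and Junb at 1.94 ± 0.35.

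The immediate early and NF-kB list was higher on day 5, with 3 of 33 (Dusp1, Fos and Junb) rising and 0 falling (11 and 0 adjusted over the list alone, adjusted p = 3.53e-16, and 0.0125 with an estimated correlation). The heat shock and unfolded protein response list was called lower (8.79e-05, and 0.0214) with no member of 25 passing, Pdia6 at -0.85 ± 0.28 (0.454; 0.00603 to 0.803) and Manf at -0.89 ± 0.31 (0.491; 0.0103 to 0.766). Both were called with library quality weights (0.00603 and 0.0103), and Manf with only the libraries of both groups (0.0358). Neutrophil markers had 1 of 15 (Il1b) rising (8 over the list alone, 3.24e-09, and adjusted p = 0.258 with an estimated correlation), and S100a8 did not pass (2.40 ± 0.69, 0.326), at 0.51 in batch 1 and 4.29 in batch 2. The neutrophil share of the normalized total was 0.307 ± 0.273% on day 1 (0.202% without replicate 1). On day 5 it was 1.37 ± 1.25% (0.934% without replicate 6). Only batch 2 separated the days, at 0.1564 to 0.2001% on day 1 and 1.726 to 3.563% on day 5. In batch 1 the day 5 shares, 0.3925 to 0.4135%, lay inside the day 1 range of 0.08895 to 0.8317%. The neutrophil list mean moved by 0.7 in batch 1 and 4.15 in batch 2. Oxidative phosphorylation had 0 of 35 passing with the list called lower (8.56e-12, and adjusted p = 0.494 with an estimated correlation), and recirculation 0 of 23 (2 rising over the list alone) with the list called higher (0.00147, and adjusted p = 0.258 with an estimated correlation). Gata3 (0.41 ± 0.60, 0.865), Rora (0.93 ± 0.73, 0.732), Il1rl1 (1.06 ± 1.13, 0.808), Klrg1 (0.62 ± 0.52, 0.758), Il7r (0.77 ± 0.71, 0.777), Il2ra (-0.08 ± 0.64, 0.999), Il10 (1.15 ± 1.11, 0.793), Ifng (0.54 ± 0.75, 0.857) and Mki67 (2.44 ± 1.22, 0.665) did not pass.

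Between the blood days limma called 15 genes higher and 1 lower (n = 6 against 6), all 16 with the same sign in both batches, with 7 genes called in batch 1 alone and 80 in batch 2 alone and 1167 at unadjusted p < 0.05. All 9 called genes named here, picked for their change in these libraries, had 6 of 6 day 5 libraries on the side of the change from the day 1 mean. There was no overlap of the groups in 8 (Foxd4 did overlap). Without blood day 1 replicate 5 the number higher was 6 and the number lower 0, and without blood day 1 replicate 2 the number lower was 6. The number higher was 9 without blood day 5 replicate 6, and the number lower was 3 without blood day 1 replicate 3, 2 without blood day 1 replicate 4, baseline replicate 5 or blood day 5 replicate 2 or 3, and 0 without blood day 5 replicate 4 or 5. Called genes higher and lower were 201 and 156 with library quality weights, 5 and 0 in edgeR with TMM scaling, 65 and 68 in DESeq2, and 9 and 0 with the closest libraries averaged. The real grouping gave 16 genes and the highest other of 100 splits 6. A grouping of the same 12 libraries by batch gave 559, with the batch term then set by the baseline and brain libraries alone.

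What separates ILC2-labelled cells of the brain from those of the blood at day 5? Otx2, a homeobox gene of choroid plexus (chr14:48657677-48673819), had a mean of 42800 (SD 53300) in brain and no read in blood, at least 14200-fold on a floor of 3 reads per library. Pex5l (at least 12000-fold), Kcne4 (10900), Fbln2 (6610) and Slco1a4 (5950) were also at 0 in blood. In batch 1 these 5 bounds were lower, at 1020, 979, 1180, 1130 and 1390. Further, Igfbp5 rose by 13.63 ± 1.14, Col3a1 by 13.29 ± 1.53 (9.39 in batch 1 and 17.18 in batch 2) and Slc47a1 by 13.15 ± 0.85. The largest falls were the platelet genes Tubb1 (-12.55 ± 1.24) and Ppbp (-12.15 ± 1.55) and the NK and cytotoxic genes Ncr1 (-12.10 ± 0.68), Prf1 (-11.05 ± 0.65), Fasl (-10.86 ± 0.61), Klra1 (-10.70 ± 0.67), Gzma (-10.70 ± 0.59) and Klra7 (-10.69 ± 0.67).

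Every tested T cell and NK cell marker fell in brain. T cell markers fell in 16 of 16 (16 over the list alone, adjusted p = 3.03e-19, and 4.73e-04 with an estimated correlation). Cd3d fell from 3760 to 13.1 and Trbc2 from 8130 to 19.8. NK markers fell in 11 of 11 (11 over the list alone, 4.57e-16, and 3.10e-04). Klrb1c fell from 16700 to 13.5. The share of T cell markers was 0.334 ± 0.0611% in blood day 5 and 0.00132 ± 0.000345% in brain, and of NK markers 1.495 ± 0.795% and 0.001295%. The ILC2 identity list fell in 14 of 23 and rose in 0 (14 over the list alone, 2.48e-09, and 0.00312), including Icos (-5.82 ± 0.33). Gata3 fell from 1590 to 13.3 (-7.26 ± 0.60), Klrg1 from 10800 to 9.40 (-10.03 ± 0.52), Il7r from 2130 to 90.6 (-4.61 ± 0.71), Il2ra from 129 to 7.06 (-4.44 ± 0.64) and Ifng from 543 to 3.28 (-7.80 ± 0.75). Rora (0.14 ± 0.73, 0.904), Il1rl1 (-1.73 ± 1.13, 0.225) and Mki67 (-0.56 ± 1.22, 0.749) did not pass. Il10 did not pass (1.89 ± 1.11, 0.176; 0.0437 to 0.475), and was called without brain replicate 4 (0.0437). The type 1 module fell in 18 of 21 and rose in 2 (18 and 2 over the list alone, 3.12e-16, and 4.73e-04). Stat4 fell by 7.96 ± 0.44. Inhibitory and costimulatory receptors fell in 16 of 24 and rose in 2 (16 and 3 over the list alone, 1.52e-09, and 8.44e-04), and the IL-2 and STAT5 list fell in 15 of 22 and rose in 2 (15 and 2 over the list alone, 1.83e-07, and 0.00266). Il2rb fell from 25500 to 32.3.

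Lists of migration genes were lower in brain as well, next to the falls of all tested T cell and NK markers. Brain libraries also held brain cell markers, so whether these falls and the rises below belong to ILC2s was not tested. Recirculation genes fell in 17 of 23 and rose in 1 (17 and 1 over the list alone, adjusted p = 1.52e-09, and 0.00312 with an estimated correlation). Chemokine receptors and integrins fell in 19 of 29 and rose in 3 (21 and 3 over the list alone, 2.46e-08, and 0.00266). Itgb7 fell from 25300 to 188. Tissue residency genes fell in 10 of 21 and rose in 2 (10 and 2 over the list alone, 5.58e-04, and 0.0142). Cd69 fell by 4.62 ± 0.47. Interferon-stimulated genes fell in 14 of 32 and rose in 3 (14 and 3 over the list alone, 0.00134, and adjusted p = 0.154 with an estimated correlation), and MHC class II genes fell in 7 of 10 and rose in 1 (8 and 1 over the list alone, 6.98e-04, and adjusted p = 0.292 with an estimated correlation). Trophic and repair factors rose in 11 of 17 and fell in 0 (11 over the list alone, 0.0259, and adjusted p = 0.0941 with an estimated correlation): Spp1 from 372 to 170000 (SD 172000) and Grn by 3.40 ± 0.38. Extracellular matrix genes rose in 16 of 26 and fell in 5 (17 and 5 over the list alone, 0.0429, and adjusted p = 0.325 with an estimated correlation), but the list was not called with the closest libraries averaged. Col1a2 rose by 11.30 ± 1.05. Heat shock genes rose in 15 of 25 (16 over the list alone, 0.0528), a list called with the closest libraries averaged. Hspb1 rose by 7.61 ± 0.64 and Hspa1b by 4.54 ± 0.56, and hypoxia targets rose in 10 of 21 and fell in 2 (10 and 2 over the list alone, 0.597).

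Cell type markers of the tissue of origin moved with it. Oligodendrocyte markers rose in 15 of 15 (15 over the list alone, adjusted p = 1.60e-06, and 0.123 with an estimated correlation), with Pdgfra at least 2640-fold higher on 3 reads per library (2240 in batch 1). Microglia markers rose in 14 of 15 (14 over the list alone, 7.82e-06, and adjusted p = 0.121 with an estimated correlation). Fcrls rose by 9.18 ± 0.84. Choroid plexus and ependymal markers rose in 10 of 10 (10 over the list alone, 6.69e-06, and adjusted p = 0.0687 with an estimated correlation), from 0.00419% (8.88e-04% without blood day 5 replicate 5) to 4.09% of the normalized total, with Kl up 11.77 ± 1.08. Foxj1 had 1 read in blood, a ratio of 31600 (95% counting interval 5680 to 1250000). Astrocyte markers rose in 13 of 14 (13 over the list alone, 6.10e-05, and adjusted p = 0.123 with an estimated correlation), and endothelial markers rose in 11 of 14 and fell in 2 (11 and 2 over the list alone, 0.0199, and adjusted p = 0.292 with an estimated correlation). B cell markers fell in 14 of 15 (14 over the list alone, 1.36e-11, and 0.0388). Cd79a fell from 30400 to 52.5. Platelet markers fell in 12 of 12 (12 over the list alone, 4.40e-09, and adjusted p = 0.123 with an estimated correlation), erythroid markers in 7 of 8 (7 over the list alone, 1.63e-05, and adjusted p = 0.0941 with an estimated correlation) and neutrophil markers in 13 of 15 (14 over the list alone, 7.30e-07, and adjusted p = 0.123 with an estimated correlation).

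**Figure D4:**
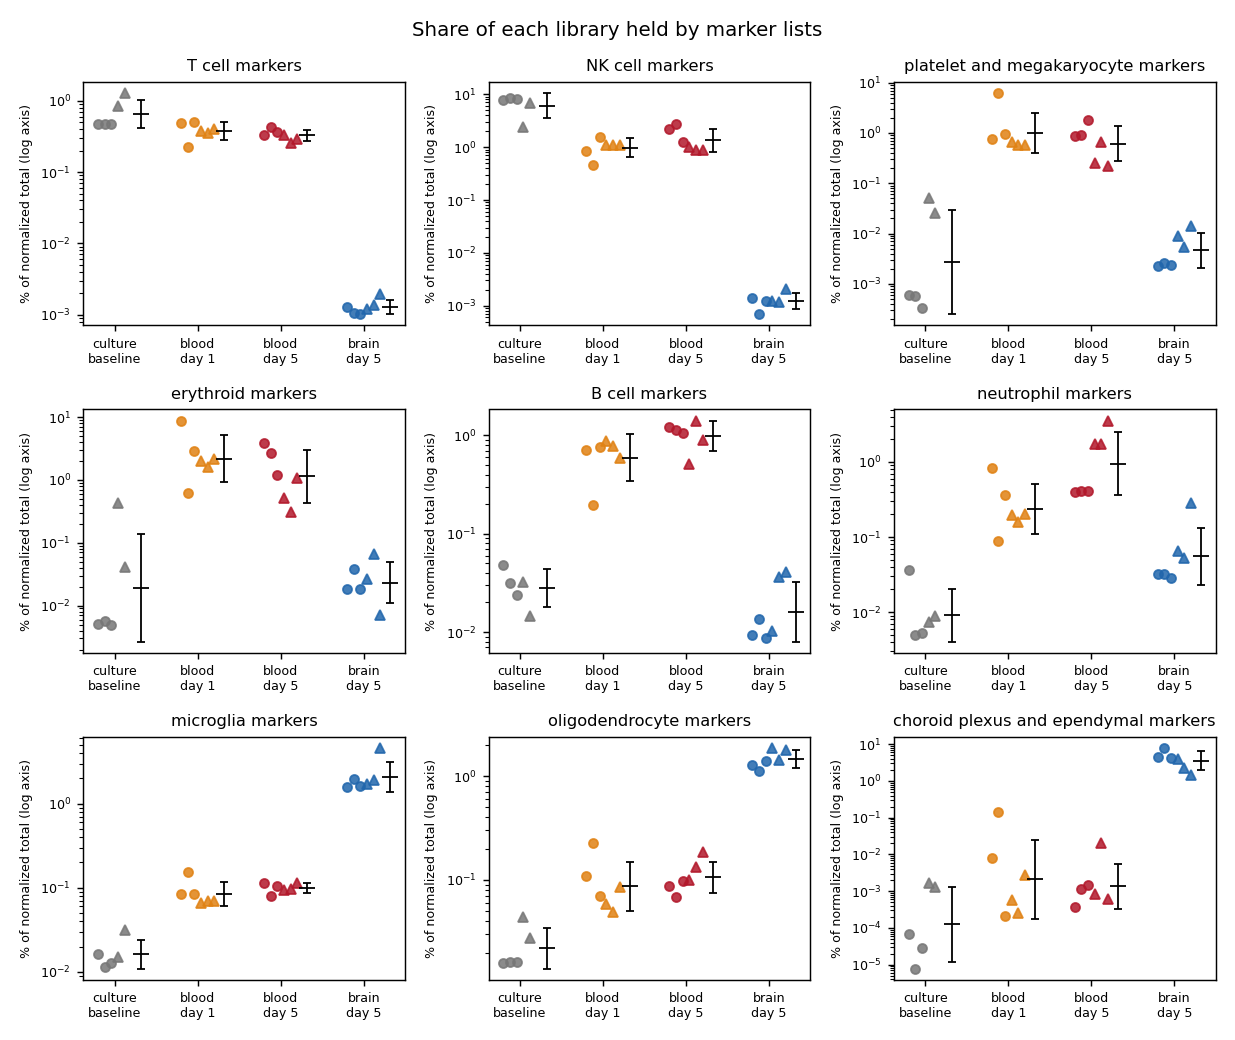
Percent of the normalized total held by 9 cell type marker lists, on a log axis, by group, with circles for batch 1 and triangles for batch 2 libraries (n = 5, 6, 6 and 6). Choroid plexus markers have a mean of 4.09% in brain against 0.00419% in blood day 5 (8.88e-04% without replicate 5), and T cell markers 0.00132% against 0.334%.

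Between brain and blood at day 5 limma called 5123 genes higher and 2183 lower in brain (n = 6 against 6), 99.3% with the same sign in both batches, with 5701 in batch 1 alone and 5751 in batch 2 alone. All 39 called genes named here, mostly picked for their change in these libraries, had 6 of 6 brain libraries on the side of the change from the blood mean, with no overlap of the groups. The share of calls that were higher was 70.1%, and 59.5% with equal library totals, a scaling that moved the median of all genes by -0.402 here and by 0.105, 0.36, -0.042 and 0.256 in blood day 1, blood day 5 and brain against culture and between the blood days. The real grouping gave the most genes of 100 splits (7306 against 5273), which excludes a random division as its source.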

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

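The tests on other cell types, on cells in the culture and on depth were chosen only after the result was seen, while the tests on overlapping genes, paralogs and random splits were written before their values were computed. The rule for T cells in the culture was changed after its result was seen: a first rule on the median alone would have excluded them, and the rule used here, the one applied to NK cells, asks every marker to lie below blood day 1.

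A library stands apart by Dixon's ratio, the gap between it and the next library as a share of the range of its group, when that share passes the 0.05 critical value for the number of libraries; the share is given here for each case. Of 469 groups of values, 70 had such a library, against 23 expected by chance at about 1 in 20 groups, and 14 of them are a gene with 1 library above 0 and the rest at 0 (share 1).

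In the baseline, replicate 4 was lowest in Mki67 (0.712), the ribosomal protein list (0.853), Canx (0.747), Gzma (0.922), Hmgcs1 (0.943), Hsp90b1 (0.84), Hspa5 (0.83), Hspe1 (0.724), Rpl23 (0.842), Sqle (0.917) and Tnfrsf9 (0.763). It was highest in Bhlhe40 (0.76) and Gpi1 (0.825) and the only one above 0 in Gp6, Klrc1 and Slc6a4 (1 each). Baseline replicate 5 was highest in Klrg1 (0.879), Il2ra (0.854) and Rps18 (0.869), alone above 0 in Aqp4 (1), and lowest in the cholesterol list (0.807), the IL-2 and STAT5 list (0.756), Cish (0.738) and Il2rb (0.889). Baseline replicate 1 was alone above 0 in Il1rl1 and Klra7 (1 each), and replicate 2 was alone above 0 in Syp (1).

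Blood day 1 replicate 2 had the most platelet transcripts, with a platelet list mean of 17.1 against 12.5 to 13.2 in the others (0.834), Gp6 (0.765) and Itga2b (0.713), and was highest in the extracellular matrix list (0.706). It was lowest in Mki67 (0.645), the G2/M (0.78), S phase (0.826), cholesterol (0.85) and MHC class II (0.778) lists, Cd79a (0.713) and Gzmf (0.66). Blood day 1 replicate 6 was lowest in the hypoxia (0.764) and trophic (0.791) lists, Asns (0.65) and Klrk1 (0.681), replicate 1 highest in Foxd4 (0.844) and replicate 5 alone above 0 in Ambn (1). Blood day 5 replicate 5 was highest in the choroid plexus list (0.811), alone above 0 in Gzmf and Kl (1 each), and lowest in the type 2 effector list (0.664) and Dusp1 (0.637). Blood day 5 replicate 4 was lowest in the MHC class II (0.714) and B cell (0.655) lists. Replicate 6 of that group was highest in Apoe (0.797) and alone above 0 in Crisp1 (1), and replicate 3 was alone above 0 in Foxj1 (1) and lowest in Klra1 (0.63).

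In brain, replicate 2 was lowest in the extracellular matrix list (0.651), Col3a1 (0.689), Flt1 (0.81), Foxj1 (0.68) and Prf1 (0.643), and alone above 0 in Klra1 (1). Brain replicate 6 was highest in microglia markers, with a list mean of 15.6 against 13.8 to 14.3 (0.737), in Fcrls (0.716), S phase (0.77) and hypoxia (0.652) genes, and lowest in Gata3 (0.743), with no read. Brain replicate 1 was lowest in Klrb1c (0.77) and Tnfrsf9 (0.704), replicate 4 highest in Cd79a (0.636) and replicate 5 alone above 0 in Ambn (1).

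Also drawing a closer look were the 16 genes between the blood days, the 7306 between brain and blood at day 5, and the falls in brain of Gata3 (-7.26), Klrg1 (-10.03), Il7r (-4.61), Il2ra (-4.44) and Ifng (-7.80). In each of the 5 comparisons the real grouping was the only one of 100 splits to give as many genes (1 of 100, the real one included), and the highest other number was 3460, 3459, 5746, 6 and 5273 in the order of the report. A grouping of the 12 blood libraries by batch gave 559 genes, in a model whose batch term was then set by the baseline and brain libraries alone. These genes differ between batches in blood otherwise than in those groups, so 559 and 16 are not like counts. The same kind of grouping of the brain and blood day 5 libraries gave 0.

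The first pattern is transcripts of other cells: Gata3, Klrg1 and T cell markers fall in brain while brain cell markers rise. Of 68 members of 5 brain cell lists 63 were higher in brain than in blood day 5, and of 50 members of 4 blood cell lists 44 were higher in blood day 1 than in culture. These counts restate the pattern, so they cannot tell for RNA from resident brain cells or from other blood cells. Brain libraries held choroid plexus, microglia, oligodendrocyte and astrocyte markers together, at mean shares of 4.09, 2.24, 1.48 and 0.686%. Blood day 1 held erythroid (3.01%, 1.85% without replicate 1), platelet (1.61%, 0.708% without replicate 2) and B cell (0.654%) markers. Markers of such unlike cell types together argue against a change of the ILC2s alone as the source of these rises. The scaling of the deposited table is excluded, since with equal library totals the T cell markers still fell by a median of -8.69 (SD 1.56, and -8.69 with genes at 0 set to their bound). Brain libraries held Klrg1 at 1.9 to 23.4 and Gata3 at 0 to 22.2, against 4366.6 to 22019.9 and 1269.8 to 1895.4 in blood day 5. T cell and NK markers held mean shares of 0.00132 and 0.0013% in brain. These values argue against lymphocyte RNA like that of blood day 5 as a large part of the brain libraries. The exact amount of RNA from other cells was not estimated. A difference of the ILC2s themselves between tissues, besides such RNA, was not tested and stays open, as the share of ILC2s in each library is not known.

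The second pattern is a baseline with T cell receptor and granzyme transcripts and almost no Il1rl1 or Il7r. The labels describe a sort with ST2 and CD127 after culture, and whether the baseline passed it is not stated in the sources used here. For T cells in the culture the data cannot tell: 9 T cell markers outside the receptor complex had a median of -6.07 against blood day 1 (-9.72 to 3.59), 7 of them more than 2 log2 units lower, with Lck at 53.8 and Cd6 at 17.8, but Themis was higher, 2036 against 413, and the 7 receptor complex genes had a median of 1.22. The 7 NK receptor genes had a median of -10.17 against blood day 1 (-12.59 to -6.12, and -10.17 with bounds). This argues against NK cells with receptor levels like those of blood. The test left out Gzma, Prf1, Eomes and Ccl5, and the NK list was already known to be higher in blood. That list held 6.70% of the normalized total in the baseline, and NK cells with few of these receptors cannot be told. Loss of Il7r reads in counting is excluded, since the lowest blood day 1 value was 369.8 and the highest baseline value 75.8. A change of ILC2s in culture was not tested and stays open.

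The third pattern is 99 genes with 0 reads in every batch 1 library and reads in every batch 2 library, among them Tuba1b with 4203 expected reads. There were 0 genes the other way, which the genes held by the table fixed: 1137 genes were at 0 in every batch 1 library, and no gene in every batch 2 library. Paralogs or pseudogenes fit by the rule set in advance, with 20.2% of the genes (20 of 99) sharing sequence with a non-overlapping gene against 0.6% of 500 others (Fisher's exact p = 4.74e-14). The 500 others were not matched for gene class or length, while many of the 99 are small RNA genes. The test therefore cannot tell shared sequence from gene class, and the 14 genes with at least 30 expected reads were not tested apart. Overlapping exons cannot be told, with 77.8% (77 of 99) against 39.3% of 8270 others (Fisher's exact p = 1.16e-14), a ratio just under the bound of 2 set in advance. Lower depth is excluded for 14 genes with at least 30 expected reads and cannot be told for the other 85. Many of the 85, such as Mir671 and Snord78, had a batch 2 mean of 0.6 and a lowest count of 1 read, where 1 read was worth 0.383 to 0.749. Those genes held close to 1 read in every batch 2 library, a count that did not follow depth. How each batch was counted is not given in the sources used here, and no biological explanation was tested.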

How the results depend on the processing

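The edgeR, DESeq2, 4-library, zero-gene and averaged-library alternatives were chosen only after the result was seen. Of 204 named gene values under 16 alternatives, 3205 outcomes stayed the same, 31 were weaker and 12 stronger, while 16 values had no adjusted p in DESeq2 and could not be compared there, and leaving out each library in turn gave 4659 the same, 29 weaker and 4 stronger. Apart from those of the fixed genes, these values were chosen for large changes or small p, which favours the same outcome. No called value reversed its sign, while 16 uncalled gene values and 21 uncalled lists did. The number of lists called moved only with an estimated correlation, where it went from 28, 27, 21, 11 and 28 to 5, 5, 6, 2 and 10 (blood day 1, blood day 5 and brain against culture, blood day 5 against blood day 1, brain against blood day 5). Between the blood days the main 15 genes higher and 1 lower became 201 and 156 with library quality weights, 65 and 68 in DESeq2, 5 and 0 in edgeR with TMM scaling, 9 and 0 with the closest libraries averaged, and 9 higher with only the libraries of both groups. The number lower was 0 with a replicate block and with a pseudocount of 5, and 5 without the 4 libraries standing apart. Leaving out a library gave 6 to 20 higher and 0 to 6 lower: 6 higher and 0 lower without blood day 1 replicate 5, 20 higher without replicate 1, and 6 lower without replicate 2. Also, the number higher was 10 without blood day 1 replicate 4 or blood day 5 replicate 5 and 9 without blood day 5 replicate 6, and the number lower 3 without blood day 1 replicate 3, 2 without blood day 1 replicate 4, baseline replicate 5 or blood day 5 replicates 2 or 3, and 0 without blood day 5 replicates 4 or 5. Quality weights gave 5274 higher and 4647 lower for blood day 1 against culture, 5133 and 4500 for blood day 5, and 3054 lower for brain. In blood day 1 against culture, 1370 were lower with only the libraries of both groups and 1222 with the closest libraries averaged, 1177 of them among the main 2135, and in brain against culture edgeR with TMM called 2746 lower. For blood day 5 against culture, 1155 were lower with equal library totals and 2802 without the 4 libraries, 1692 of them among the main 1748. Ifng in blood day 5 against culture was called in DESeq2 (0.0349, 6.18e-05 to 0.482 over the alternatives), with quality weights (6.18e-05), with only the libraries of both groups (7.99e-04) and without the 4 libraries (0.0345), and Foxd4 between the blood days was not called in DESeq2 (0.509). With the closest libraries averaged Gata3, Ifng and Mki67 lost their calls in blood day 1 against culture (0.126, 0.25 and 0.221), and Foxd4 and Dmxl2 between the blood days (0.0634 each). Apart from settings that hold fewer libraries, the cause of these changes was not tested. Recovered reads ran from 11.6 M to 58.1 M per library (M, 1e6 reads), and the effect of depth on these counts was not tested.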

Other observations

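The lists were all fixed in advance, while the list means by batch and the averaged libraries were chosen only after the result was seen. Il5 did not reach the level for testing, with means of 0.361 in the baseline, 0.414 in blood day 1, 2.83 in blood day 5 (0.647 without replicate 6, which held 13.8) and 0.311 in brain, and the effector list held 0.00917% of the normalized total in the baseline and 0.0424% in brain. Of 12 effector genes tested, 2 rose and 3 fell in blood day 1 against culture (2 and 3 adjusted over the list alone, list test 0.949, its sign opposite to that of the median and mean). In blood day 5 against culture 4 rose and 2 fell (5 and 2, 0.794), in brain against culture 7 rose and 1, Il10, fell (7 and 2, 0.679), and in brain against blood day 5 4 rose and 0 fell (4 and 0, 0.731). None passed between the blood days (0.483). Penk, a member of this list and of the trophic list, accounts for one of the rises in brain against culture (8.64 ± 0.94).

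Genes of ribosome biogenesis fell in 6 of 29 and rose in 1 in blood day 1 against culture (5 and 1, 0.0473, and adjusted p = 0.468 with an estimated correlation, 0.271 with the closest libraries averaged; list mean -1.2 in batch 1 but 0.39 in batch 2), and fell in 11 in brain against culture (11, 1.42e-05, and adjusted p = 0.145 with an estimated correlation; list mean -1.43 in batch 1 but 0.21 in batch 2). Oxidative phosphorylation genes rose in 6 of 35 and fell in 1 in blood day 1 against culture (2 and 0, 0.861), and rose in 9 of 35 in brain against blood day 5 (8, 0.374). Apoptosis and p53 targets rose in 4 of 24 and fell in 8 in each blood group against culture (4 and 9 on day 1, 0.187, and 4 and 8 on day 5, 0.205), with no list call in any comparison and, in both brain comparisons, a test sign opposite to the median and mean. Nuclear-retained RNAs had 0 of 6 passing in either blood group against culture (0.343 on day 1, and 0.78 on day 5 with the sign of the test opposite to that of the median and mean) and 2 of 6 rising in brain against culture (2, 0.915) and against blood day 5 (2, 0.699). Of the mitochondrial transcripts 1 of 13 is in the table, and no list test was run.

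Interferon-stimulated genes rose in 16 of 32 and fell in 1 in blood day 5 against culture (17 and 1, 3.28e-05, and adjusted p = 0.071 with an estimated correlation). Hypoxia targets there fell in 6 of 21 and rose in 1 (7 and 2, 6.43e-04, and adjusted p = 0.0955 with an estimated correlation). Tissue residency genes did not pass as a list in blood day 1 (9 rose and 4 fell of 21, 0.25) or blood day 5 (9 and 3, 0.0799) against culture. Microglia markers rose in 9 of 15 in blood day 1 (9 and 1 falling, 2.48e-04, and adjusted p = 0.176 with an estimated correlation) and 10 of 15 in blood day 5 (10, 6.29e-05, and adjusted p = 0.14 with an estimated correlation).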
